A study of Mus musculus with 37 samples.

How the data were processed

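Total RNA of mouse embryo fibroblast lines was labelled with Cy3 and Cy5 by reverse transcription, per the labels' protocols, and hybridised to arrays of 21888 spots printed from amplified inserts of mouse embryo cDNA libraries. The series holds 37 arrays: 32 of a wild-type line against a menin-null line, 2 of pooled RNA and 3 of an RNA against itself. The scanner tables deposited by the authors give, per the file headers, mean SR and SG intensities with background means and deviations, a calibrated ratio and a quality score. The deposited intensities were found to be already background-subtracted. The ratio deposited by the authors equalled SR over SG divided by a constant for each array. The series matrix deposited by the authors holds log2 of that ratio where the quality score was at least 0.5, with 100% of values equal within 0.001. Its columns are not centred (medians from -0.51 to 0.39), and its direction is that of SR over SG, with the RNA in each channel open as described in the report. Scanner, image software and the method of background subtraction are not given in the sources used here. Each slide held 1 array and no scan date was used, so no batch could be tested. The slide numbers of each wild-type line form a block of their own, while those of each null line spread over all blocks.

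Of the spots, 19993 were clone spots, 384 a housekeeping mix, 768 unnamed spots after the last clone, 630 wells with no clone and 113 wells marked empty, and all but the clone spots were left out. Leaving out wells with no clone was decided after the files were examined. Clones were named through the platform table: 12567 clone spots had 1 symbol, 694 had several and 6732 none. A further 180 spots took the symbol of a clone with the same title and 70 had a title that reads as a gene name, and no gene was named from a spot with several symbols. The 223 spots that share a clone with another spot were averaged, which left 19861 distinct clones. Of the platform table's symbols 0 needed an update, and list symbols were replaced by current names where these differ.

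Log2 ratios of SR over SG were computed with values below 1 set to 1, and normalized within each array by loess (span 0.3, 4 iterations, limma 3.58.1 in R 4.3.3) fitted on clone spots with a quality score of at least 0.5. Spots under that score were left out. The design planned normexp with an offset of 50 unless the intensities were already corrected, and since they were, they were used as deposited. The array labelled 10W against 12N forward nearly equalled that labelled 10W against 17N forward (log2 ratio r = 0.987, intensity rho = 0.9986, next highest pair 0.985) and correlated at 0.25 with its own dye swap, where other pairs gave 0.675 to 0.906. It correlated at 0.855 with the swap of 10W and 17N. Both were therefore averaged and counted as 10W against 17N.

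The cell line was the replicate. For each clone measured on at least 24 of the arrays and at least 4 per line, least squares on the 8 lines and a dye term gave 1 value per line, centred on their mean. Limma (lmFit and eBayes) then compared 4 null with 4 wild-type line values, with Benjamini-Hochberg adjustment over 18757 clones and an adjusted p under 0.05. The median SD between lines of a genotype was 0.189 and the median residual SD between arrays 0.164. The line values keep some noise from the arrays, so the test is conservative where that noise dominates: of unchanged simulated clones, 1.07% came under an unadjusted p of 0.05 with array noise alone and 4.22% with the line spreads seen here. A fold is that of the brightest clone of a gene, which also stands for the gene in lists. Both channels of the genes named in the null against wild-type comparison exceeded 2.6 background deviations on every array that measured them, apart from the null channel of Nox4 (28 of 30), the wild-type channel of Hspb1 (30 of 31) and the null channel of Igfbp3 (30 of 31). No group missed this limit on all arrays, so no fold was given as a bound. Wells with no clone or marked empty nevertheless had a median log2 brightness of 8.18. The clones of Nox4 (7.79), Hoxc9 (7.70), Nefl (7.82), Xist (7.77) and Alpl (7.63) were dimmer, so differences of clones this dim may be compressed.

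Lists and rules were fixed before the data were examined. The named genes were Men1, up to 12 per direction among genes past the threshold with the same sign in all 16 pairs, filled up by smallest p, and up to 4 members per list. Within that limit, list members with an unadjusted p under 0.05 were taken, or else the 1 of smallest p, a narrowing made after the files were examined, and the matrix trio and the menin and MLL target genes were named in full. The result of 1 list member is not reported here. AW553219, genes named as neighbours, the macrophage genes and the imprinted and Y-linked genes in the comparison among lines were named after their values were seen. Of 38 lists with 828 genes, 526 genes were measured, and 37 lists had at least 3. Lists were tested with camera (correlation 0.01), with an estimated correlation, and with fry. Differences among lines used limma's moderated F over the arrays. Each test was adjusted on its own.

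The procedure was tested on simulated arrays for 18757 clones with the spreads seen here. For the null against wild-type comparison, 10 of 50 clones changed by a log2 size of 0.5 were recovered, 39 of 50 at 1, 48 of 50 at 2 and 50 of 50 at 4, with 8 unchanged clones called. Far more clones were called there than the 2 in the data, which makes the adjusted threshold easier to reach. Recovery in the data may therefore be lower, and Fbln2 (-3.78) and Hspb1 (3.67) missed the threshold in the data. A list of 30 of 8488 genes was recovered, with 0 random lists called, but these simulated genes were drawn independently. Among null lines, 1.84% of simulated clones with no line differences and 71.9% of those with differences were called. Alternatives covered background, normalization, quality, dye, brightness, replicate unit, thresholds, list tests and leaving out each line.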

Results

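Gene expression was compared between mouse embryo fibroblast lines with and without menin, the nuclear scaffold protein encoded by Men1, on glass arrays of printed cDNA clones read in 2 colours. Fibroblasts are the connective tissue cells that grow out of a dissociated embryo. There were 4 wild-type lines (10W, 26W, 46W and 50W) and 4 menin-null lines (12N, 17N, 40N and 47N). Each wild-type line was hybridised against each null line in both dye orientations, which gave 32 arrays over 16 pairs of lines. A further 2 arrays compared pooled wild-type with pooled null RNA, and 3 arrays compared an RNA sample with itself. The median intensity per array ranged from 129 to 910 in the SR channel and from 102 to 896 in the SG channel, and 64.6% to 97.8% of the clone spots on an array had usable quality. The dimmest array was the forward array of 46W and 12N. The arrays labelled 10W against 12N forward and 10W against 17N forward differed by less than repeat hybridisations of the same pair did (r = 0.987 across clones, next highest pair 0.906), so their mean was counted as 1 array and 31 arrays entered the fits. The cell line was the replicate, so p-values between genotypes set their difference against the spread between lines of a genotype. The 4 lines per genotype limit the precision.

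All signed values below are null minus wild type on the log2 scale, in the direction that is likely from the labels. Every line array ran the same way whatever its dyes (r between a forward array and its own swap of 0.677 to 0.919), so SR holds 1 genotype throughout. The labels list the wild-type RNA as channel 1 on all line arrays, which places it in SR if SR is channel 1. The dye patterns do not settle this. If SR is channel 1 on the self arrays too, the pool arrays point to null RNA in SR (r with the mean self array of -0.51 forward and 0.52 swapped) and the line arrays, more weakly, to wild type (median r of 0.062 forward and -0.079 swapped). If SR is the Cy5 signal on the self arrays, these readings exchange. With the sign turned, every rise and fall would exchange, as would the lines that stand high and low for a gene, while sizes, numbers of calls and p-values of the comparisons would stay as they are.

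The first comparison asks which transcripts the loss of menin changes in these fibroblasts. Men1 itself was 3.69-fold lower in the null lines: it fell by 1.88 on the log2 scale (SE 0.10, n = 4 and 4 lines, limma adjusted p = 0.00098), and the difference had the same sign in 16 of 16 pairs. The 16 pairs share lines, so they are not independent, and 265 of the 18757 clones tested had the same sign in all 16. The SR channel was brighter on each of the 31 line arrays at the Men1 clone, by 1.26 to 2.31. With the sign turned, Men1 would be 3.69-fold higher in the menin-null lines, in 16 of 16 pairs, which argues against that direction. It does not settle the direction, because whether the printed Men1 clone lies in the deleted part of the gene is open. The only other clone past the threshold was AW553219, which carries no gene name and fell by 1.37 (SE 0.11, limma adjusted p = 0.012, lower in 16 of 16 pairs). It came from the source well next to that of the Men1 clone. Together these were 2 of the 18757 clones tested, both lower in null and none higher, which corresponds to 1 of 8488 named genes. At an unadjusted p under 0.05, 1029 clones passed against 938 expected with no difference, 475 higher and 554 lower in null. The call of AW553219 was lost without 50W (-1.39, limma adjusted p = 0.122), without 12N (-1.34, 0.0846) or without 40N (-1.39, 0.0634), while its difference stayed about as large. That of Men1 was lost in the limma fit to 4 disjoint pairs of lines (adjusted p = 0.0995), where its difference also stayed about as large. That fit, to 1 of the possible pairings, called 0 clones.

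Among the genes lower in the null lines that missed the threshold, the matrix glycoprotein Fbln2 and the lipoprotein lipase activator Apoc2 came closest. Fbln2 differed by -3.78 (SE 0.42, 13.8-fold, n = 4 and 4 lines) and Apoc2 by -2.52 (SE 0.27, 5.75-fold), both lower in 16 of 16 pairs with a limma adjusted p of 0.0575. The Apoc2 clone was printed on the spot beside Fbln2, which is the brighter of the pair. An unnamed clone followed with -3.58 (SE 0.40, adjusted p = 0.0575). Its line values lay close to those of Fbln2 (2.51 against 2.46 in 26W, -2.48 against -2.75 in 12N), so it may not be a separate fall. Fbln2 and Apoc2 passed at an adjusted p of 0.0128 and 0.0095 in the authors' series matrix values and of 0.0331 with a trended, robust variance prior. Nox4, an NADPH oxidase that makes hydrogen peroxide, differed by -1.92 (SE 0.32). Pcyt1a, the rate-limiting enzyme of phosphatidylcholine synthesis, differed by -0.83, and its other clones by -0.94, -0.87 and -0.60. The remaining genes of smallest p on this side were the zinc finger gene Bnc2 (-0.81), the ubiquilin gene Ubqln2 (-0.81), Ccdc122 (-0.71), the methyltransferase gene Setd6 (-0.58), AI413582 (-0.54), Prr15l (-0.46) and Nucb2 (-0.46), with adjusted p between 0.387 and 0.585. The other Ubqln2 clones did not follow (0.23 and 0.064).

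On the other side, Amot, which encodes the junction protein angiomotin, came closest to the threshold with 0.78 (SE 0.093, 1.72-fold, higher in 16 of 16 pairs, limma adjusted p = 0.0782). The small heat shock protein gene Hspb1 had the largest difference of the 12 genes named on this side, 3.67 (SE 0.63, 12.7-fold). Lgals3, which encodes a galactoside-binding lectin that macrophages also make in quantity, differed by 2.26 (SE 0.42). Its null line values were 1.83 in 17N, 1.1 in 12N, 1.08 in 47N and 0.52 in 40N. It thus did not follow the macrophage markers below, which were highest in 40N and 47N. The paternally expressed imprinted gene Peg3 differed by 1.84 (SE 0.30), and its other clones by 1.68 and 0.16. The glycogen-binding protein gene Stbd1 differed by 1.74 and 1.30 in its clones, and the receptor phosphatase gene Ptprk by 0.73 and 1.01. Zup1 (1.53), the forkhead gene Foxd1 (1.20), the catulin gene Ctnnal1 (1.01), the DNA repair kinase gene Prkdc (0.84), the DNA glycosylase gene Tdg (0.49) and the lens crystallin gene Cryga (0.47) completed this set, with adjusted p between 0.387 and 0.666 for all but Amot. The other clone of Ctnnal1 differed by 0.33, and further clones of Prkdc (0.12) and Zup1 (0.094) lay near 0. Cryga was higher in 15 of 16 pairs, and the other 11 in 16 of 16. These 12 genes were taken by smallest p, so such counts are no further support.

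**Figure D1:**
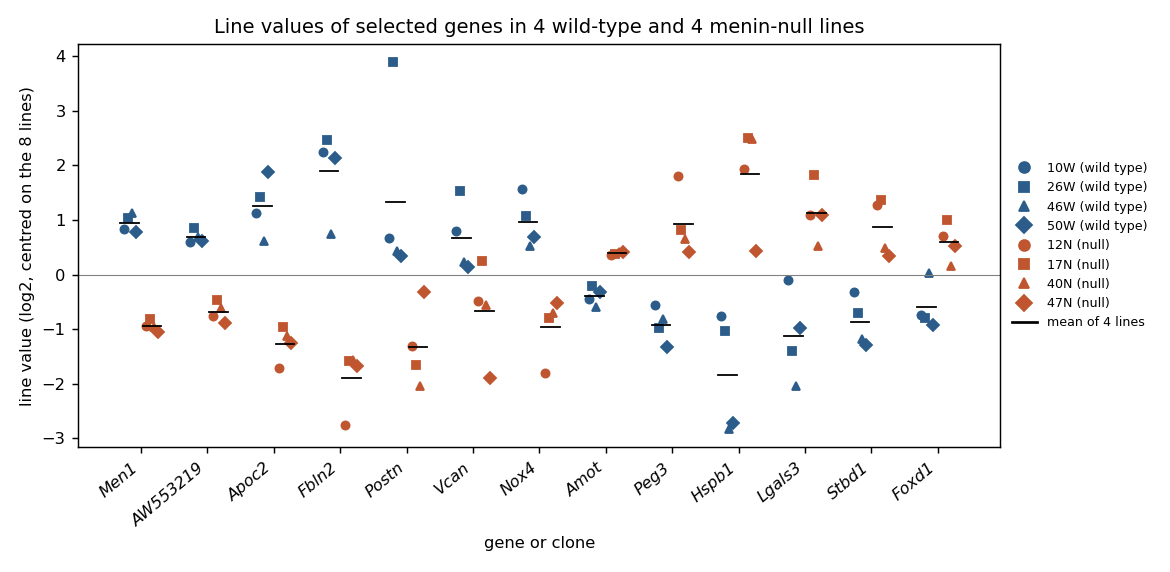
Line values (log2, centred on the 8 lines, vertical axis) of Men1, the unnamed clone AW553219 and 11 genes; each symbol is a line, blue for wild type and orange for null, and bars are means of 4 lines, in the likely direction (turned, rises and falls exchange). The groups overlap only for Vcan, where 17N (0.24) lies above 46W (0.22) and 50W (0.13), so separation does not set Men1 and AW553219 apart. Fbln2 ranges from 2.46 in 26W to -2.75 in 12N.

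Extracellular matrix genes were examined as groups fixed in advance. The trio Fbln2, Postn and Vcan, which a study of these arrays is recalled to have named, was lower (mean -2.60, camera adjusted p = 1.4e-05, and adjusted p = 0.231 with an estimated correlation). Of its 3 genes 3 passed when adjusted over the list alone and 0 over all genes, and since the study chose them on these samples this is not independent evidence. Postn, the matricellular protein periostin, differed by -2.66 (SE 0.80) and Vcan, the large proteoglycan versican, by -1.35 (SE 0.47), each lower in 16 of 16 pairs. The fitted line values of Vcan nevertheless overlapped, with null line 17N (0.24) above wild-type lines 46W (0.22) and 50W (0.13). The Postn value of 26W, 3.89, lay far above the other wild-type lines (0.33 to 0.66). Among 9 collagen genes 3 were positive and 6 negative (mean -0.56, median -0.15, adjusted p = 0.252). Col5a2 differed by -1.93 (SE 0.46) and was the 1 collagen that passed over the list alone, with 0 over all genes, and Col3a1 differed by -1.70. Collagen processing (mean 0.046), glycoproteins and elastic fibre (0.12), proteoglycans (0.031), matrix proteases and inhibitors (0.16) and cell adhesion (0.088) had adjusted p between 0.253 and 0.803. Their members of smallest p were Fkbp10 (0.38), Ltbp4 (0.77), Sdc3 (1.08), Plaur (1.05) and Itga6 (0.72). For the basement membrane list the test pointed up while mean and median were below 0 (-0.015 and -0.069, adjusted p = 0.803), and Lama5 differed by 1.0. Leaving out 46W moved the collagen mean to -0.97 (camera adjusted p = 0.0267), Sdc3 to 0.57 and Itga6 to 0.42. Leaving out 47N moved Fkbp10 to 0.19, and leaving out 26W the mean of matrix proteases and inhibitors to 0.27 (camera adjusted p = 0.0449). The collagen mean was -0.25 without 26W and -0.26 without 40N, and that of matrix proteases and inhibitors 0.046 without 47N.

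The contractile and myofibroblast genes, which encode the actin and myosin machinery of smooth muscle and activated fibroblasts, were higher as a group (mean 0.34, median 0.36, camera adjusted p = 0.00089, and adjusted p = 0.839 with an estimated correlation). Of the 18 measured, 15 were positive and 3 negative, and 0 passed by limma over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05. Those were the tropomyosin gene Tpm2 (1.35, SE 0.57) and the myosin light chain gene Myl6 (0.35, SE 0.14). Without 46W, at -2.42 the lowest line for Tpm2, Tpm2 differed by 0.76 and the list mean was 0.21. Among the null lines, 47N had the highest mean of the list (0.45, others 0.070 to 0.083). Macrophage and blood markers moved the same way without passing (mean 0.69, median 0.87, 9 of 10 positive, adjusted p = 0.053), and were led by 40N and 47N. They passed under 12 of 19 other settings with all 8 lines, and without 12N (mean 1.0, adjusted p = 0.000795), 17N (0.0043) or 50W (0.0288), while the mean was 0.34 without 47N (0.242) and 0.43 without 40N (0.279). Fibroblast and mesenchyme markers moved the other way (mean -0.43, 7 of 7 negative, adjusted p = 0.115), with the PDGF receptor gene Pdgfrb at -1.55 (SE 0.50), and a list mean of -0.22 without 26W.

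DNA replication genes were lower as a group (mean -0.13, median -0.15, camera adjusted p = 0.00851, and adjusted p = 0.839 with an estimated correlation). Of 31 measured, 26 were negative and 5 positive, and 0 passed by limma over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05. The helicase subunit gene Mcm6 differed by -0.53 (SE 0.20) and the DNA ligase gene Lig1 by -0.28 (SE 0.12). The camera call was lost without 10W (adjusted p = 0.22), 17N (0.282) or 47N (0.224). Mitosis genes followed without passing (28 of 33 negative, mean -0.14, adjusted p = 0.063), with the cyclin gene Ccnb2 at -1.37. CDK inhibitors and p53 targets were positive for 10 of 14 (mean 0.25, adjusted p = 0.0904). Among them the antiproliferative gene Btg2 differed by 1.31 and the CDK inhibitor gene Cdkn2c by -0.56. Mitosis genes passed under 6 of 19 other settings with all 8 lines, and without 40N (mean -0.25, adjusted p = 4.99e-06), 26W (0.00174) or 46W (0.0369), while their mean was -0.035 without 10W (0.852), -0.071 without 17N and -0.085 without 47N. CDK inhibitors and p53 targets passed without 26W (0.0233) and had a mean of 0.16 without 50W (0.262).

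The menin and MLL complex list holds menin, binding partners of menin and other MLL complex genes. Of its 13 measured genes Men1 alone passed, over all genes and adjusted over the list alone. With Men1 included its mean was -0.14 and its median lay at 0 (camera adjusted p = 0.658). With fry, which asks whether genes move on balance in 1 direction, the list had an adjusted p of 0.0169 through Men1. Without Men1 the other 12 genes had a mean of 0.008 and a fry adjusted p of 0.951, in a test chosen after the data were seen. The matrix trio passed with fry as well (0.0169). Of the menin and MLL target genes 8 were measured and 0 passed (mean -0.21, camera adjusted p = 0.252, and a mean of -0.13 without 46W). They were Cdkn2c (-0.56), Pbx3 (-0.95), Meis1 (-0.28), Esr1 (-0.061), Gata3 (-0.057), Hoxa5 (0.17), Hoxc9 (0.021) and Hoxd8 (0.021). In the homeobox list (mean 0.11, adjusted p = 0.658), Hoxb5 (0.71) and Hoxb3 (1.78) had the smallest p, and the list mean was 0.017 without 50W, 0.057 without 47N and 0.20 without 26W. Leaving out 1 line moved Pbx3 to -0.54 (without 46W), Meis1 to -0.17 (without 12N) and Esr1 to -0.010 (without 40N). It turned the sign of Hoxa5 (-0.18 without 10W), Gata3 (0.11 without 26W), Hoxc9 (-0.025 without 40N) and Hoxd8 (-0.26 without 50W).

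In the signalling and stress lists, named members passed only when adjusted over the list alone and never over all genes. These were Wnt5a (-1.06, SE 0.26, Wnt signalling mean -0.15, adjusted p = 0.309), Peg3 among the imprinted genes, and Hspb1 and the chaperone gene Dnaja1 (0.34, SE 0.093) in the heat shock list. The heat shock mean was 0.39 with a median of -0.002 (adjusted p = 0.253), and the imprinted genes had a mean of -0.059 and a median of -0.016 although the test pointed up (0.794). Tcf4, in the Wnt list, differed by -0.52. For the TGF-beta and BMP response the mean was -0.008 and the median -0.037 with the test pointing up (0.658). In the AP-1 and immediate early list (mean 0.09, adjusted p = 0.543) Ier3 (0.48) and Fosl2 (0.45) stood against Egr1 (-0.94). The IGF axis had a mean of -0.099, a median of 0.10 and a test pointing up (0.803), with the growth factor binding protein gene Igfbp3 at -2.38 (SE 1.03). For the interferon and MHC class I list the median was 0.029 while mean (-0.005) and test pointed down (0.955), and Oas1a (-0.41), Irf1 (-0.81) and Ifi35 (-0.33) had the smallest p. Chemokines and inflammation (mean 0.018, 0.803), with Lcn2 at 0.24, also stayed short of the threshold. Egr1 moved to -0.61 without 12N and Lcn2 to 0.072 without 17N. The mean of the IGF axis was -0.0077 without 26W and -0.20 without 47N, that of the AP-1 and immediate early list 0.047 without 10W and 0.15 without 50W, and that of Wnt signalling -0.093 without 40N.

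Metabolic and housekeeping lists did not pass with all 8 lines and the normalization used here. Of 19 other settings with all 8 lines, cholesterol and lipid synthesis passed under 10, oxidative phosphorylation under 4 and glycolysis and hypoxia under 1. Cholesterol and lipid synthesis genes were negative for 10 of 12 (mean -0.31, adjusted p = 0.053), with the isomerase gene Idi1 at -0.86 (SE 0.45). Glycolysis and hypoxia genes (mean 0.15, adjusted p = 0.115) included Ero1a at 0.65, and oxidative phosphorylation genes (mean -0.063, adjusted p = 0.115) included Cox7b at -0.23. The ER stress and chaperone list (0.11, adjusted p = 0.477) included Atf4 at 0.35, and the oxidative stress response (0.004, 0.803) included Txn1 at 0.46. Ribosomal protein genes had a mean of 0.023 and a median of -0.001 (0.794), with Rpl36 at -0.17, and the sex-linked list had a median of -0.033 (0.803), with the Xist clone at 0.12. Cholesterol and lipid synthesis passed without 46W (mean -0.48, adjusted p = 3.87e-06), 47N (0.00275) or 12N (0.0459), and ribosomal proteins without 47N (mean 0.15, 1.65e-05) or 26W (0.00661). Oxidative phosphorylation passed without 40N (0.0219), 26W (0.0241) or 50W (0.0247), and glycolysis and hypoxia without 50W (0.0288) or 12N (0.0459). In the other direction, the mean was -0.20 for cholesterol and lipid synthesis without 26W, -0.065 for ribosomal proteins without 17N, and 0.0053 for oxidative phosphorylation and 0.074 for glycolysis and hypoxia without 46W. The ER stress and chaperone mean was 0.013 without 47N, 0.040 without 10W and 0.17 without 40N. Idi1 moved to -0.54 without 26W and -1.33 without 46W, Txn1 to 0.27 without 46W and Xist to 0.072 without 50W. Markers of other cell types lay near 0 or varied: epithelium (mean 0.034, Spint2 0.23), skeletal muscle (0.064, Myl1 0.13), cartilage and bone (0.11, Alpl 0.12) and adipocyte (0.37, Lpl 0.61) each had an adjusted p of 0.614. The adipocyte mean was 0.098 without 46W, 0.21 without 47N and 0.57 without 50W, and the cartilage and bone mean -0.16 without 46W and 0.24 without 26W or 50W. Neural and glial markers had a mean of 0.08, a median of -0.01 and a test pointing down (0.978), with Nefl at -0.15. Of the endothelium list 2 genes were measured, too few to test, with Cdh5 at -0.18. Leaving out 1 line moved Spint2 to 0.12 (17N), Myl1 to 0.053 (40N), Alpl to 0.015 (47N), Lpl to 0.34 (47N), Nefl to 0.016 (26W) and Cdh5 to -0.063 (46W). Camera with its preset correlation called 3 of 37 lists, and 0 with an estimated correlation.

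**Figure D2:**
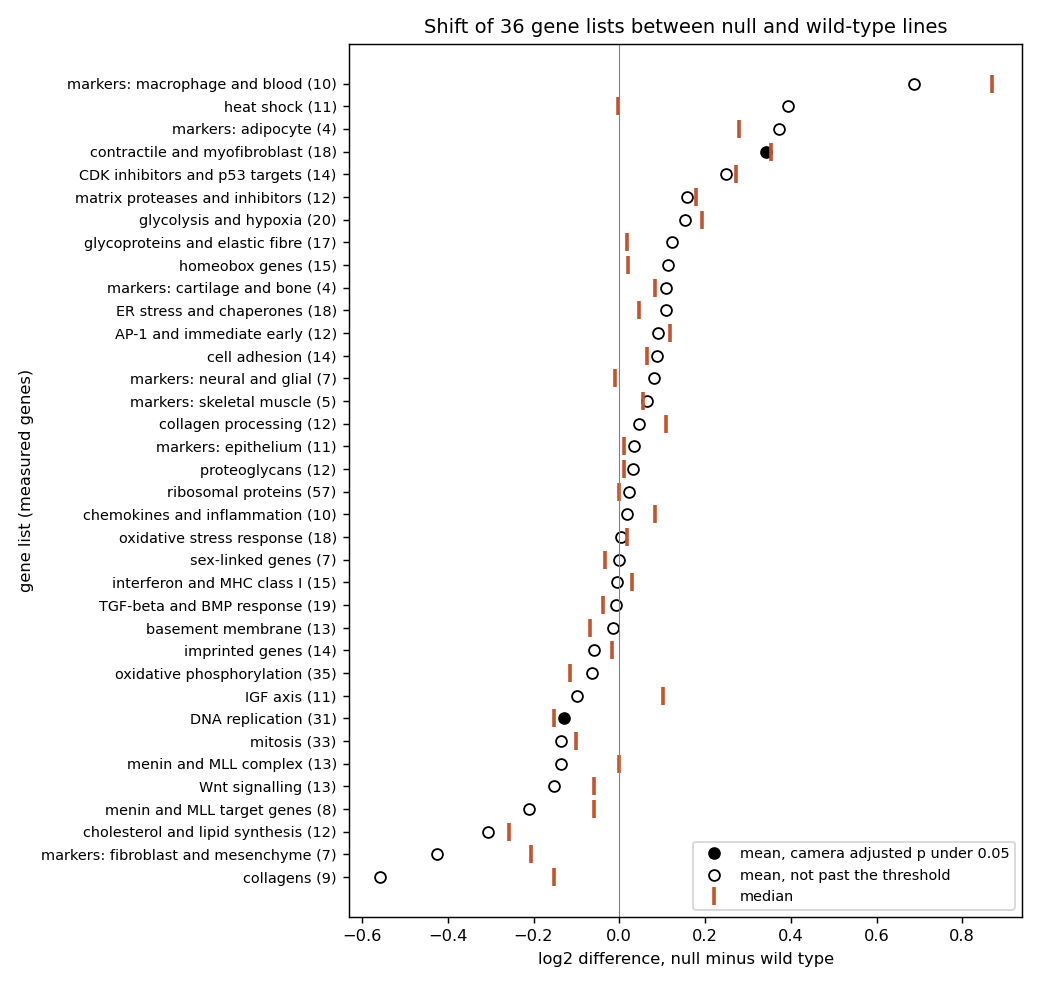
Mean (circle) and median (orange tick) log2 difference, null minus wild type in the likely direction, for 36 gene lists, with the number of measured genes in brackets; filled circles passed camera at an adjusted p under 0.05. Contractile and myofibroblast genes (mean 0.34) and DNA replication genes (mean -0.13) are the filled ones, and neither passed with an estimated correlation; turned, rises and falls exchange.

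Differences among the lines of the same genotype were large. Among the null lines 14043 clones (74.9%) differed by limma's moderated F at an adjusted p under 0.05, among the wild-type lines 13458 (71.8%), and 11448 clones differed in both. These tests set the RNA samples against the spread between hybridisations and do not compare conditions. The slides of each wild-type line form a block of their own, from 30 to 37 for 26W, 38 to 47 for 10W, 55 to 62 for 46W and 63 to 70 for 50W, so differences among wild-type lines cannot be separated from slide run. The null line 47N carried high values of Acp5, a phosphatase of osteoclasts and macrophages (3.11, others -0.51 to -0.42), and of Spp1, the secreted phosphoprotein osteopontin (3.17, against -1.93 in 17N). The lysozyme gene Lyz2 ranged over 4.94 among null lines, with 2.65 in 40N and 3.18 in 47N against -1.76 in 12N and -1.63 in 17N, and the complement gene C1qa over 4.30 (2.52 and 2.87 against -1.43 and -1.12). In wild-type line 50W Lyz2 stood at 1.95 and C1qa at 0.57, against -1.64 to -1.28 and -1.23 to -1.06 in the other wild-type lines. Further wide ranges among null lines were seen for Rsrp1 (5.69), the proteoglycan gene Bgn (4.42), the protease gene Adamts1 (4.18), the hyaluronan-binding protein gene Cemip (3.93), Galnt18 (3.92), the Wnt inhibitor gene Dkk3 (3.86) and the cytochrome gene Cyp1b1 (3.83). A clone named Cdk8 ranged over 4.62 with nearly the profile of the Spp1 clone (r = 0.999 over the 8 lines), so its name is uncertain here.

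Among the wild-type lines, 46W stood apart for several of the widest-ranging genes. The type I collagen genes were low in 46W, with Col1a2 at -3.58 against 1.78 to 3.01 in the other wild-type lines (range 6.59) and Col1a1 at -3.83 against 0.15 to 1.70 (range 5.53). The lipid droplet gene Plin2 was also low there (-3.59). The hedgehog coreceptor gene Cdon (3.32), the imprinted gene Mest (3.68), the basement membrane gene Nid2 (2.78), the semaphorin gene Sema3c (2.99) and Cemip (3.14) were high. The proteoglycan gene Dcn ranged from -2.34 in 50W to 2.20 in 26W and Bgn from -2.11 in 46W to 2.68 in 26W. Cd24a was highest in 10W (1.75) and the intermediate filament gene Nes lowest in 26W (-3.17). The imprinted genes H19 (2.37) and Dlk1 (1.64) were highest in 26W. The Y-linked gene Eif2s3y was above 0 in 10W (0.80), 46W (0.79), 12N (0.88) and 40N (0.43) and below 0 in the other lines (-1.24 to -0.48), and Ddx3y was above 0 in 10W (0.87), 12N (1.08) and 40N (0.72) but at -0.64 in 46W. Collagen genes had a median range of 2.69 among wild-type lines against 0.43 for all named genes.

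**Figure D3:**
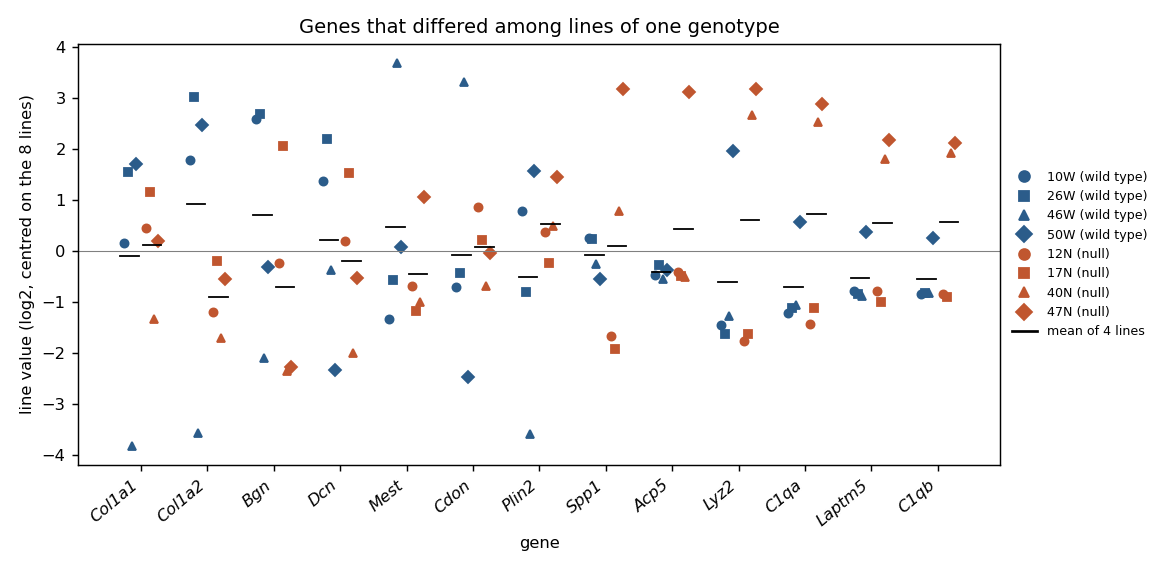
Line values (log2, centred on the 8 lines, vertical axis) of genes that differed among lines of the same genotype; each symbol is a line, blue for wild type and orange for null, and bars are means of 4 lines, in the likely direction (turned, high and low exchange). Col1a1 and Col1a2 are lowest in 46W, and Lyz2, C1qa, Laptm5 and C1qb are highest in 40N and 47N.

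The pooled RNA asked whether a mixture of lines gives the differences of the single lines. Across 15775 clones the mean of the 2 pool arrays followed the line values (Pearson r = 0.875, Spearman rho = 0.804), though clones are not independent replicates, the pools are 1 replicate, and the labels do not say which lines they hold. Of the 24 genes named above for smallest p, 12 of 12 on the higher side and 10 of 10 measured on the lower side kept their sign. So did 79.6% of all 15775 clones, and 99.2% of the 953 clones with an unadjusted limma p under 0.05. The named genes therefore did not stand apart from other clones of small p. In the pools Men1 differed by -1.60, Fbln2 by -3.69, Apoc2 by -2.88, Hspb1 by 3.66 and Lgals3 by 2.02, and Postn by -3.88. The forward and swapped pool arrays had a correlation of 0.004 across clones with each other, against 0.652 and 0.567 with the mean line array. Pcyt1a came out at -1.53 on the forward and 0.19 on the swapped array.

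The self arrays gave the noise of a hybridisation without a biological difference. The SD of log2 ratios was 0.20 for the wild-type pool, 0.22 for the null pool and 0.17 for line 50W against itself, while the line arrays ranged from 0.36 to 0.60. Beyond 2-fold lay 0.0601% to 0.107% of clones on self arrays, and 1.87% to 7.58% on line arrays. The Men1 clone lay between -0.092 and 0.19 on the self arrays.

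**Figure D4:**
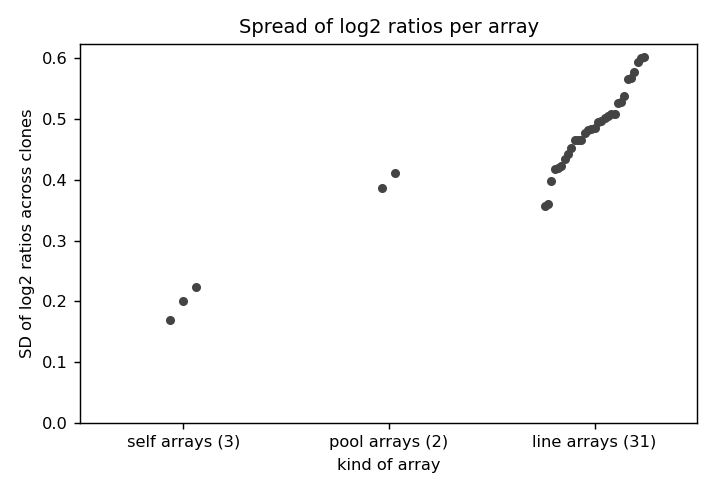
SD of the normalized log2 ratios across clones (vertical axis) for each of 3 self arrays, 2 pool arrays and 31 line arrays, each point an array, ordered by value within its kind. The self arrays lie between 0.17 and 0.22 and the line arrays between 0.36 and 0.60.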

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

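The count of splits for clones, the p of Men1 at each split, the share of near-identical pairs, the genes singled out in the set of clones and the comparison of spots along the printed row with those above and below were chosen after the result was seen, and the other tests of this part were written before theirs.

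Of 230 groups of 4 line values examined, 18 held a line far from the other 3, where chance gives about 1 in 20 groups, or 11.5. Among wild-type lines the value of 26W stood apart for Postn (3.89, others 0.33 to 0.66), Nefl (0.56, others -0.12 to -0.051), Fcer1g (-0.67, others -0.26 to -0.18) and the mean of matrix proteases and inhibitors (0.25, others -0.20 to -0.17). The value of 46W stood apart for Sdc3 (-2.06), Cdkn2c (0.80), Lpl (-0.74) and the skeletal muscle markers (0.054). That of 50W stood apart for Dnaja1 (0.024), Rpl36 (0.050) and the macrophage and blood markers (0.27, others -0.62 to -0.48), and that of 10W for the mean of DNA replication genes (0.28, others -0.024 to 0.0085). Among null lines this held for 12N in Fbln2 (-2.75, others -1.67 to -1.57), for 17N in Irf1 (0.16) and Lcn2 (0.64), and for 40N in Pdgfrb (-2.32, others -0.36 to -0.088). It held for 47N in Alpl (0.38) and the contractile and myofibroblast mean (0.45, others 0.070 to 0.083). Of the 743 wells marked as empty or without a clone, 724 were brighter than 95% of the 768 unnamed spots (median log2 brightness 8.18 against 1.63, and 8.86 for clone spots), and what they hold was not tested.

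The number of clones called between genotypes cannot be set apart from other groupings of the 8 lines, since 3 of the 35 splits into 4 and 4 gave at least as many (2 for the genotypes, 101 for the highest other). For the Men1 clone, the only clone examined at each split, limma gave p = 5.21e-08 for the genotype split and 0.0803 as the smallest of any other split. For gene lists, 28 of the 35 splits called at least the 3 lists of the genotype split, and the highest other called 10, so chance cannot be excluded for their number. For differences among lines only chance between hybridisations was tested, as each line is 1 RNA sample, and this can be excluded: of 100 regroupings of the array labels, the real one included, 1 gave as many clones among null lines (14043, highest other 4658) and 1 among wild-type lines (13458, highest other 1871). The slides of each wild-type line form a block, so slide run is not excluded for differences among wild-type lines.

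The split with 101 clones sets 10W, 46W, 12N and 47N against the other lines, which points to a structure of the samples that crosses genotype. Of these clones 95 were higher in the 4 lines, by a median of 1.21, and they were bright (median log2 brightness 12.1 against 8.98). Clones matched on brightness, taken from outside the set of 95, shifted by -0.019 times as much, which argues against brightness as the cause. Other clones of the same genes (54 clones of 36 genes) shifted by -0.003 times as much. They too were taken from outside the set, but no named gene had more than a single clone in it. A transcribed sequence carried by most of these clones would give this. The other clone did follow for Ikbkg (0.62 against 0.601 in the set) and Smpd4 (0.452 against 0.439), and in part for Fnip1 (0.347 against 0.591). What the sequence is stays open, and no biological explanation was tested.

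Both clones that fell, Men1 and AW553219, came from neighbouring source wells (profile r = 0.989), and Apoc2 was printed beside Fbln2 (profile r = 0.984). The other 3 clones in wells next to the Men1 well had a median difference of 0.045, and next to strongly varying clones in general the profile correlation was 0.029 above that 3 wells away, both against a general carry-over between neighbouring wells. Near-identical profiles (r over 0.95) nevertheless occurred in 1.31% of 839 next-well pairs and 0% of 659 pairs 3 wells away, so whether AW553219 is a clone of the same transcript or holds material of the Men1 well stays open. For Apoc2, the other 2 spots beside Fbln2, those above and below, had a median of -0.035, against signal that spreads to all sides, but spots beside bright varying spots in the same row followed them (correlation 0.163 above that 3 spots away), and this excess was 0.095 larger than for spots above or below. Signal from Fbln2 along the row, a shared transcript and a real fall of Apoc2 cannot be told apart, because each gene has only this named clone.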

How the results depend on the processing

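The fits to all 32 arrays as labelled, with normexp, without the dimmest array and of the menin list without Men1 were chosen after the data were seen, and all other alternatives before the data were examined. No paired analysis was possible because the labels give wild-type and null lines no shared replicate numbers. The alternative that limits the pools to called clones gave no value, since 2 clones allow no correlation. Of 2178 values of named genes and clones, 2003 kept direction and side of the threshold, 148 passed newly, 5 no longer passed and 22 turned sign. Of 1000 values of gene lists, 853 stayed, 56 passed newly, 10 no longer passed and 81 turned sign. Both clones called were among those called under each change of background, normalization, quality, dye term or orientation. The counts of clones among null lines and among wild-type lines, the pool correlation (0.885 without the dimmest 25% of clones) and the self arrays stayed on the same side of their limits. Without normalization the median of all clones moved to 0.12, and shifts there are relative to it. For the changes that follow the cause was not tested, apart from counts that rest on fewer lines or on more values treated as independent. The count of clones, 2, became 5 with Aquantile channels, series matrix values, forward arrays alone, a trended robust prior or without the dimmest 25% of clones, and 6 with swapped arrays alone or an adjusted p under 0.10. It became 1029 at an unadjusted p under 0.05, 3232 with 16 pairs as replicates, 6445 with each array as a replicate, both of which ignore shared lines, and 0 by limma with 4 disjoint pairs (1090 at an unadjusted p under 0.05), where Men1 kept -1.83 at an adjusted p of 0.0995. Leaving out each line gave 1 (without 50W, 12N or 40N) to 10 (without 46W). The count of lists, 3, became 5 with no background correction, print-tip loess, scaling or all spots kept, 6 with all clones of a gene or 32 arrays, 7 with median centring, no normalization or Aquantile, 8 with the series matrix, and 2 (without 10W) to 8 (without 26W) leaving out lines. It became 0 with an estimated correlation, where the matrix trio (-2.60), DNA replication (-0.13) and contractile genes (0.34) no longer passed, the latter 2 not with fry either, while the menin and MLL complex (-0.14) passed with fry. Without Men1 its mean was 0.0083, with an adjusted p of 0.794 by camera and 0.951 by fry. DNA replication also missed with swapped arrays alone (-0.10) and contractile genes without normalization (0.42).

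Macrophage and blood markers passed without background correction (0.52), with normexp (0.66), print-tip loess (0.69), median centring (0.68), scaling (0.71), Aquantile (0.69), the series matrix (0.71), all spots (0.68), 32 arrays (0.69), all clones (0.70), and without the dimmest array (0.69) or the dimmest clones (0.77). Cholesterol and lipid synthesis passed with no background correction (-0.24), print-tip loess (-0.31), median centring (-0.34), no normalization (-0.22), scaling (-0.33), Aquantile (-0.31), the series matrix (-0.30), all spots (-0.29), 32 arrays (-0.31) and all clones (-0.31). Mitosis passed with median centring (-0.16), no normalization (-0.041), Aquantile (-0.14), the series matrix (-0.13), 32 arrays (-0.15) and all clones (-0.14). Oxidative phosphorylation passed with median centring (-0.10), the series matrix (-0.073) and forward arrays (-0.14), collagens (-0.49) without normalization, and fibroblast markers without normalization (-0.34) and with the series matrix (-0.43). Glycolysis and hypoxia passed with swapped arrays (0.20) and CDK inhibitors and p53 targets with Aquantile (0.25). The sign of the mean turned for sex-linked genes with no background correction (-0.012), normexp (-0.0032), median centring (-0.031), scaling (-0.0095), Aquantile (-0.0069), the series matrix (-0.0016), all spots (-0.0033), no dye term (-0.0011), swapped arrays (-0.043), 32 arrays (-0.0041), all clones (-0.016) and without the dimmest array (-0.0025) or the dimmest clones (-0.020). It turned for oxidative stress with median centring (-0.029), scaling (-0.0051), forward arrays (-0.064) and 32 arrays (-0.0011), and for chemokines with print-tip loess (-0.0016), median centring (-0.014) and forward arrays (-0.012). It turned for proteoglycans with median centring (-0.0092), scaling (-0.0082) and all clones (-0.0070), and for ribosomal proteins with median centring (-0.020) and forward arrays (-0.049). Without normalization the values of basement membrane (0.071), the TGF-beta response (0.081), imprinted genes (0.038), interferon (0.10), oxidative phosphorylation (0.017), Esr1 (0.0021) and Gata3 (0.066) came out above 0, but all lay below the median of all clones there (0.12), so none turned relative to it, and oxidative phosphorylation passed as lower (p = 0.0203). Interferon also turned with the series matrix (0.0044), all spots (0.00036) and swapped arrays (0.029), where oxidative phosphorylation (0.017) and Gata3 (0.0081) did too. The TGF-beta response turned with forward arrays (0.0039) and all clones (0.0032), and basement membrane with all clones (0.044). Hoxd8 turned with scaling (-0.039), 32 arrays (-0.035) and disjoint pairs (-0.081), Gata3 (0.052) and Xist (-0.016) with disjoint pairs, and Hoxc9 (-0.023) and Nefl (0.023) with forward arrays.

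Leaving out 1 line, these lists passed anew by camera (adjusted p): without 26W matrix proteases (0.0449), mitosis (0.00174), CDK inhibitors and p53 targets (0.0233), oxidative phosphorylation (0.0241) and ribosomal proteins (0.00661); without 46W collagens (0.0267), mitosis (0.0369) and cholesterol (3.87e-06). Without 50W these were glycolysis (0.0288), oxidative phosphorylation (0.0247) and macrophage markers (0.0288), without 12N glycolysis (0.0459), cholesterol (0.0459) and macrophage markers (0.000795), and without 17N macrophage markers (0.0043). Without 40N they were mitosis (4.99e-06) and oxidative phosphorylation (0.0219), and without 47N cholesterol (0.00275) and ribosomal proteins (1.65e-05). Leaving out each line in turn moved the mean of collagens from -0.97 to -0.25, collagen processing from -0.059 to 0.19, basement membrane from -0.18 to 0.10, glycoproteins and elastic fibre from -0.038 to 0.27, proteoglycans from -0.087 to 0.17, matrix proteases from 0.046 to 0.27 and cell adhesion from -0.021 to 0.15. DNA replication ranged from -0.22 to -0.056, mitosis from -0.25 to -0.035, CDK inhibitors and p53 targets from 0.16 to 0.31, the TGF-beta response from -0.11 to 0.075 and imprinted genes from -0.26 to 0.11. Interferon ranged from -0.090 to 0.076, chemokines from -0.13 to 0.13, glycolysis from 0.074 to 0.20, oxidative phosphorylation from -0.10 to 0.0053, cholesterol from -0.48 to -0.20 and oxidative stress from -0.056 to 0.088. Ribosomal proteins ranged from -0.065 to 0.15, sex-linked genes from -0.053 to 0.068, and markers of macrophages and blood from 0.34 (without 47N) to 1.0 (without 12N), of skeletal muscle from -0.00055 to 0.10, of neural cells from -0.0053 to 0.19, of cartilage from -0.16 to 0.24, of adipocytes from 0.098 to 0.57 and of epithelium from 0.0022 to 0.067. The IGF axis ranged from -0.20 to -0.0077, homeobox genes from 0.017 to 0.20, ER stress from 0.013 to 0.17, AP-1 from 0.047 to 0.15, menin and MLL target genes from -0.31 to -0.13, Wnt signalling from -0.21 to -0.093, fibroblast markers from -0.52 to -0.22 and contractile genes from 0.21 to 0.50. Among genes Hoxa5 ranged from -0.18 to 0.35, Hoxc9 from -0.025 to 0.062, Gata3 from -0.27 to 0.11, Hoxd8 from -0.26 to 0.28 and Nefl from -0.21 to 0.016.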

Other observations

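The test of macrophage genes over 40N and 47N alone and the count without Fcgr1 were chosen after the result was seen, and that over 3 lines before.

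Among 10 measured macrophage and blood markers, those of macrophages varied together across lines, and the bright red cell clone Hbb-b1 did not follow them. In 47N and 40N the lysosomal gene Laptm5 stood at 2.17 and 1.79, the complement genes C1qb at 2.12 and 1.92 and C1qc at 1.84 and 1.62, and the Fc receptor chain gene Fcer1g at 1.45 and 0.42. The lines 10W, 26W, 46W, 12N and 17N lay at or below -0.79 for Laptm5 and at or below -0.82 for C1qb. The globin gene Hbb-y lay between -0.057 and 0.045 in all 8 lines, and Alas2, which starts haem synthesis in red cell precursors, between -0.21 and 0.27. The brightest globin clone, Hbb-b1, ranged from -0.68 in 26W to 0.81 in 17N, and Hba-x from -0.44 in 17N to 0.19 in 50W. The clones of Hbb-y (log2 brightness 8.26), Alas2 (8.17) and Hba-x (7.51) were about as dim as wells with no clone (median 8.18). They therefore cannot show whether red cell genes follow, and only Hbb-b1 (10.63) bears on this.

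A candidate explanation is that some cultures hold macrophages, which grow out of embryos with fibroblasts, and a second list of 50 macrophage genes, 18 of them measured, was written before it was examined and had to lie over 0.25 in 40N, 47N and 50W. Its lowest median over the 3 lines was -0.038, in 50W, which argues against that account for all 3 together, although the other 5 lines lay lower still (-0.24 to -0.15), so 50W stays open. Of this list, Cybb, Vav1, Was, Cd48, Dok2 and Plek (log2 brightness 7.06 to 7.95) were dimmer than wells with no clone (median 8.18). Their differences may be compressed, though they enter the medians and counts that follow. In 40N and 47N the medians were 0.38 and 0.46, with 15 and 17 of 18 genes above 0 (15 and 16 of 17 without Fcgr1, whose clone belongs to the set of 95 clones that follow another pattern), among them Mpeg1 (1.08 and 1.37), Fcgr3 (1.15 and 1.62) and Alox5ap (1.24 and 1.11). In the likely direction of the ratio, macrophages in these 2 null lines are consistent with that lower value of 0.382. With the sign turned, 40N and 47N would have the lowest values and macrophages would be placed in the other lines. That reading would also make Men1 3.69-fold higher in the menin-null lines, which argues against it without settling the direction. A macrophage-like programme in the fibroblasts themselves was not tested.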
